A study of Mus musculus with 12 samples.

How the data were processed

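RNA was measured in CD103+ and CD11b+ dendritic cells sorted from the kidneys of 6 wild-type male mice aged 8 to 12 weeks, 3 healthy and 3 killed 7 days after nephrotoxic antiserum. The 12 libraries formed 4 groups of 3 biological replicates. Per the labels' protocols, kidneys were digested with DNase and collagenase at 37 °C, leukocytes were enriched with CD45 beads, cells were sorted into lysis buffer and RNA was treated with DNase. Libraries were made with a SMARTer Ultra Low kit and 12 PCR cycles and sequenced as 50-base single reads, per the labels' protocols. Both subsets were collected from each mouse, but the labels do not say that a library's number marks the mouse.

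The deposited log2 values were 1 table of 26281 lines for the 12 libraries. Per the submitters' processing notes, STAR 2.0.4b, Subread, featureCounts 1.4.5 and edgeR were used, without their role or order, and the genome build is not given in the sources used here. In every library 2 to the power of the value, times 1 library-specific size, less 0.5 reads, gave whole numbers for 100% of genes within 0.05, so the values were read as log2 CPM with an offset of 0.5 reads and a scaled library size. Whole reads were recovered in this way, and scaling factors ran from 0.921 to 1.081. After 160 repeated lines were dropped 26121 genes remained, of which 26004 IDs are in the GENCODE M21 annotation of GRCm38. That annotation supplied coordinates and restored 27 symbols that had been turned into dates. CPM in the text are recovered reads per scaled library size.

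Genes with a value of at least 0, that is at least 1 CPM, in at least 3 libraries were tested, which kept 14180 and left out 11941. The deposited log2 values were fitted with limma 3.58.1 in R 4.3.3, with 1 mean per group over the 12 libraries and trended, robust empirical Bayes. Tests were two-sided, with Benjamini-Hochberg adjustment within each comparison and a threshold of 0.05. The 5 comparisons were inflamed against healthy in CD103+ and in CD11b+ cells, CD11b+ against CD103+ in healthy and in inflamed kidneys, and the difference between the responses of the subsets. Comparisons set side by side in the overlaps share no libraries, but both subsets came from each mouse. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

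Gene lists were fixed before the data were examined: 33 lists with 633 members, 623 of them found, cover cell types, presentation, costimulation, maturation, cytokines, chemokines, regulatory T cell support, interferon, Toll-like receptor and NF-kB genes, Fc receptors, lectins, cell cycle, metabolism, matrix and stress. Of these, 32 had at least 5 measured genes and were tested with limma's camera at its preset correlation of 0.01, adjusted over lists within a comparison; the erythroid and platelet list had 2 measured genes and was not tested. Members higher and lower were counted over all genes and adjusted over the list alone. Named genes are the 8 largest rises and the 8 largest falls per comparison between 2 groups with adjusted p under 0.05, no overlap of libraries and at least 10 CPM in the higher group, with unnamed gene models and immunoglobulin or T cell receptor segments passed over. For the difference of responses they are the 6 largest each way. Some of the genes picked by these rules are not reported here and were not replaced, but they stayed in every fit and list. Up to 4 members per list with the smallest adjusted p and 10 identity genes were also named, while Ptprc and the use of Gpx3 as a summary were chosen after their values were seen. A fold against a group with 0 reads is a lower limit from 3 reads over the group, and with 1 to 3 reads it is a ratio of reads with a 95% counting interval.

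The script was tested on simulated data with known changes, in libraries drawn from the real means and sizes. Of genes changed 1.5-, 2- and 4-fold, it recovered 12.1%, 28.8% and 75.4% for CD103+ cells in nephritis (14411 genes), 20.0%, 41.5% and 80.6% for CD11b+ cells in nephritis (14280 genes), 15.2%, 55.6% and 83.1% between the healthy subsets (14234 genes), 20.3%, 45.3% and 83.3% between the inflamed subsets (14109 genes) and 1.54%, 32.3% and 74.2% for the difference of responses (14384 genes). False calls were 0%, 7.22%, 1.98%, 4.90% and 5.33% of the calls in the same order. Each percentage recovered rests on 62 to 66 changed genes, and all other genes were simulated without a change. Far more genes passed in the real comparisons, so these rates may not hold for them.

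Alternatives fixed beforehand were a pseudocount of 0.25 or 4 CPM, no filter, at least 5 CPM in 3 libraries, median-centred libraries, quantile normalization, array weights, only the groups compared, a replicate block, a random replicate block and leaving out each library; for lists, camera with an estimated correlation and limma's fry; and for overlaps, adjusted p under 0.01. Alternatives added after the data were seen were leukocyte scaling, the mean level of the tubule markers as a covariate, limma-voom on recovered reads, protein-coding genes only, and removal of a trend on GC content and length (splines with 4 degrees of freedom). All 12 libraries were used.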

Results

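Dendritic cells were sorted from the kidneys of 6 wild-type male mice and their RNA was sequenced. Of these mice, 3 were healthy and 3 were killed 7 days after an injection of nephrotoxic antiserum, which binds the glomerular filter and brings on the immune kidney disease called nephrotoxic nephritis. CD103+ cells and CD11b+ cells were collected from each mouse, which gave 4 groups of 3 libraries. CD103 is the integrin encoded by Itgae and is carried by the cross-presenting cDC1 lineage, while CD11b is the integrin encoded by Itgam and is carried by the cDC2 lineage, by monocytes and by macrophages. Nephritic samples are called inflamed here. The title of the series concerns opposing roles of dendritic cell subsets in glomerulonephritis. The subsets were therefore compared with each other in each state and each subset was compared across states. The difference between the responses of the subsets was tested.

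Totals of 13.9 M, 20.8 M and 15.8 M reads were recovered for healthy CD103+ libraries and 11.5 M, 19.5 M and 16.6 M for healthy CD11b+ libraries. They were 21.5 M, 20.2 M and 24.3 M in inflamed CD103+ libraries and 19.9 M, 23.8 M and 26.6 M in inflamed CD11b+ libraries. At these depths a gene with 3 reads in a library stood at 0.112 to 0.254 CPM (reads by scaled library size), the limit that a count of 0 allows. Intervals and limits of this kind cover counting error only, because PCR reads without molecular identifiers are not independent molecules. Below, levels are mean CPM ± SD over n = 3 libraries, differences are log2 values ± SE, and adjusted p values for genes come from limma with Benjamini-Hochberg adjustment over 14180 genes. Every gene named as one of the largest changes of a comparison between 2 groups had all 3 libraries of one group above all 3 of the other. This was not required for the difference of responses.

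The sorted samples held different amounts of kidney tubule transcript. The 15 tubule markers made up 4.28 ± 0.954% of the values in healthy CD103+ samples (SD, n = 3), 1.24 ± 0.588% in healthy CD11b+ samples, 0.420 ± 0.0312% in inflamed CD103+ samples and 0.511 ± 0.131% in inflamed CD11b+ samples. Gpx3, a secreted antioxidant enzyme made by the proximal tubule, was the most abundant of them and stood at 30150 ± 6539, 8521 ± 4701, 2507 ± 444 and 2974 ± 536 CPM in the same order. Ptprc, which encodes the pan-leukocyte protein CD45, ran the other way at 324 ± 156, 964 ± 166, 1254 ± 58.4 and 1590 ± 113 CPM. The mean log2 level of 39 leukocyte genes was 6.14 ± 0.55 in healthy CD103+ samples, 7.52 ± 0.10 in healthy CD11b+ samples, 7.72 ± 0.03 in inflamed CD103+ samples and 7.86 ± 0.04 in inflamed CD11b+ samples. Transcripts of the mitochondrial genome made up 9.84% to 12.1% of reads in healthy CD103+ libraries, 3.19% to 3.77% in healthy CD11b+ libraries and 1.71% to 2.20% in inflamed libraries. CD103+ healthy library 2 had the highest tubule share, 5.05%, and the lowest leukocyte level, 5.55, against 6.24 and 6.64 in the other two of its group.

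Because of this, each comparison was also computed after every library had been shifted to the same mean of the 39 leukocyte genes, a scaling chosen after the data were examined and called leukocyte scaling below. It moved the median log2 change of all genes from 0.16 to -1.42 for CD103+ cells in nephritis and from 0.08 to -0.26 for CD11b+ cells in nephritis. It moved that median from 0.02 to -1.35 between the healthy subsets, from 0.01 to -0.12 between the inflamed subsets and from -0.07 to 1.17 for the difference of responses. The comparison of the inflamed subsets was thus moved least by this scaling.

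**Figure D1:**
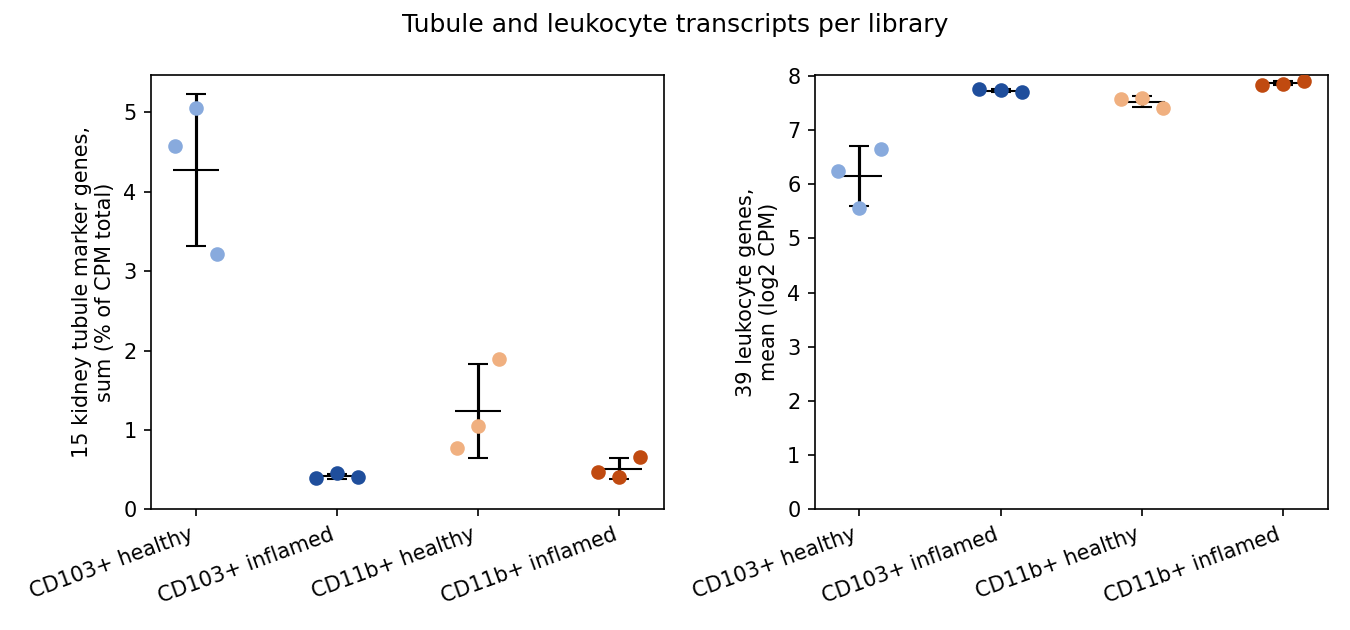
Share of 15 kidney tubule markers (percent) and mean log2 CPM of 39 leukocyte genes, one point per library, with bars for the mean ± SD of each group of 3. The tubule share averages 4.28% in healthy CD103+ samples and 0.420% in inflamed CD103+ samples, while the leukocyte level averages 6.14 and 7.72.

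The genes that define the subsets separated the sorts in both states. Itgae (ENSMUSG00000005947, chromosome 11, 73090583 to 73147446 in the GENCODE M21 annotation of GRCm38) stood at 91.9 ± 31.7 CPM in healthy CD103+ cells against 2.22 ± 0.904 CPM in healthy CD11b+ cells, and at 1034 ± 178 against 4.82 ± 0.207 CPM in inflamed kidneys (n = 3 each). Itgam (ENSMUSG00000030786, chromosome 7, 128062640 to 128118491) stood at 1.75 ± 0.260 against 124 ± 8.53 CPM in healthy kidneys and at 6.89 ± 0.375 against 315 ± 26.5 CPM in inflamed ones. Exons of Itgam overlap those of other genes over 68.7% of their length, and how the authors counted such reads is not given in the sources used here. Xcr1 (ENSMUSG00000060509, chromosome 9, 123852315 to 123862029), the receptor of the chemokine XCL1 and a cDC1 marker, was 17.1-fold lower in CD11b+ than in CD103+ cells of healthy kidneys (log2 difference -4.10 ± 0.28, limma adjusted p = 1.44e-07). In inflamed kidneys it was 237-fold lower (-7.89 ± 0.28, limma adjusted p = 2.92e-10). Clec9a, a receptor for dead cells, and Irf8, the transcription factor required by the cDC1 lineage, were also lower in CD11b+ cells in both states. They differed by -3.21 ± 0.30 and -2.77 ± 0.24 in healthy and by -5.51 ± 0.30 and -3.94 ± 0.24 in inflamed kidneys on the log2 scale. Irf4, a transcription factor of cDC2, and Sirpa, a cDC2 surface marker, were higher in CD11b+ cells, by 5.65 ± 0.26 and 3.10 ± 0.25 in healthy and by 3.15 ± 0.26 and 5.45 ± 0.25 in inflamed kidneys. Batf3, a cDC1 transcription factor, and Flt3 and Zbtb46, the receptor and the transcription factor shared by conventional dendritic cells, did not pass between the healthy subsets (-0.46 ± 0.25, -0.10 ± 0.25 and 0.11 ± 0.31). With leukocyte scaling all 3 passed and Zbtb46 turned to -1.26. Without CD103+ healthy library 2, Batf3 (-0.77) and Flt3 (-0.46) passed as well. Batf3 also passed with array weights (-0.49) and with the trend on GC content and length removed (-0.58). In inflamed kidneys all 3 were lower in CD11b+ cells, Batf3 by -2.52 ± 0.25, Flt3 by -2.44 ± 0.25 and Zbtb46 by -1.39 ± 0.31 (limma adjusted p = 5.02e-06, 9.71e-06 and 0.00517).

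**Figure D2:**
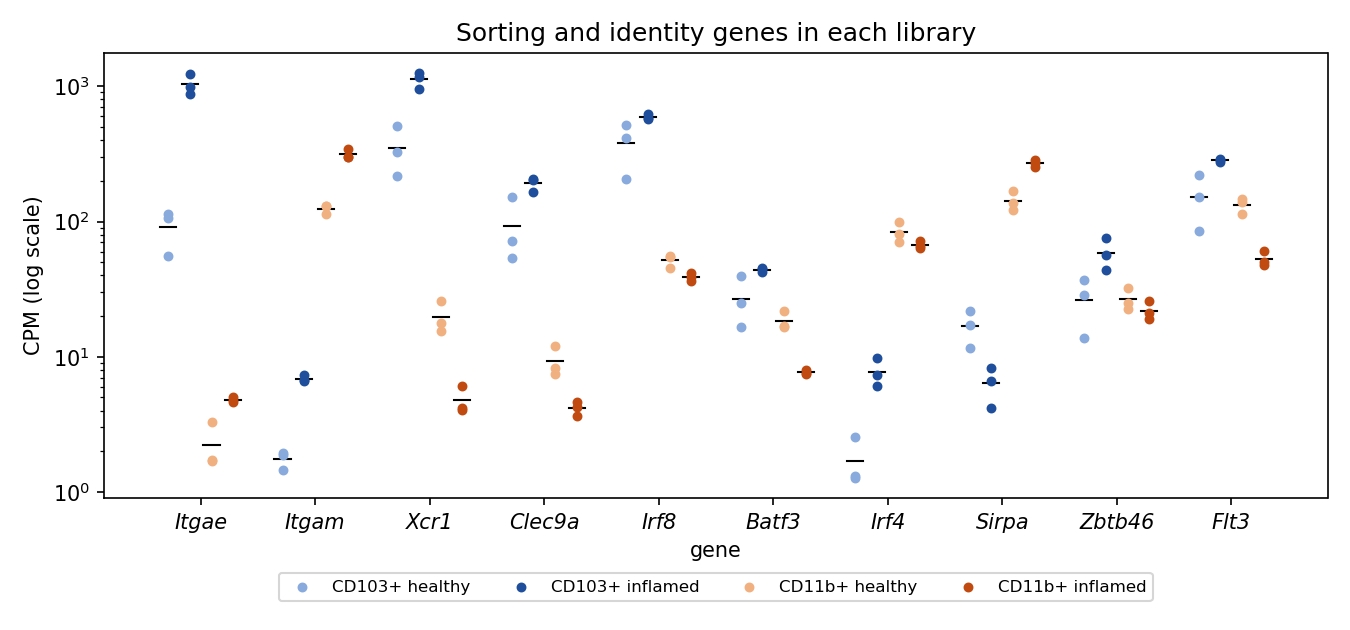
CPM of 10 subset genes on a log axis, one point per library in 4 groups of 3, with a bar for each group's mean. Itgae and Xcr1 stand at 1034 and 1123 CPM in inflamed CD103+ cells and below 5 CPM in inflamed CD11b+ cells.

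In healthy kidneys the question was how the subsets differ at rest. Clec10a, a lectin that binds galactose-type sugars, averaged 394 ± 30.0 CPM in CD11b+ and 2.46 ± 0.416 CPM in CD103+ cells (SD, n = 3 each; log2 difference 7.32 ± 0.15, limma adjusted p = 1.65e-12). Its neighbour Mgl2 reached 1685 ± 112 against 11.9 ± 4.63 CPM, and the pathogen lectin Cd209a reached 421 ± 32.4 against 3.32 ± 1.28 CPM. CD103+ cells had more Il12b, the shared p40 chain of the cytokines IL-12 and IL-23 (15.9 ± 10.7 CPM; log2 difference -5.44 ± 0.72), and more Cd207, the lectin langerin (77.9 ± 29.9 against 2.09 ± 1.63 CPM).

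Among the largest differences toward CD11b+ cells, Cadm3, an adhesion protein, was at least 180.1-fold higher, from the limit set by 0 reads over the CD103+ group. Sirpb1b, a signalling receptor of myeloid cells, was 760-fold higher by reads (95% counting interval 136 to 30040). Tlr7, the endosomal sensor of single-stranded RNA, was 314-fold higher by reads (86.6 to 2601). Cd300lb, an activating receptor of myeloid cells, and Clec4e, the Mincle receptor for mycobacterial glycolipid, were higher by 7.95 ± 0.96 and 7.74 ± 1.01 on the log2 scale. Cd209b, the SIGN-R1 lectin of macrophages, Emilin2, an extracellular matrix protein, and Retnla, the alternative-activation protein RELM-alpha, were higher by 7.83 ± 0.93, 7.81 ± 0.58 and 7.51 ± 0.57. Toward CD103+ cells, the differences were -5.61 ± 0.67 for Gramd2, -5.36 ± 0.82 for the peptidase Naalad2, and -5.00 ± 0.44 for Ttc39a. They were -4.73 ± 0.48 for the motor protein Kif5a and -4.56 ± 0.31 for the sorting nexin Snx22, whose exons overlap other genes over 28.5%.

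By list, 19 of 22 cDC2 identity genes were higher in CD11b+ cells and 3 lower, the same counts adjusted over the list alone (median log2 difference 3.24; limma's camera adjusted p = 1.42e-31, and adjusted p = 0.0496 with an estimated correlation, the only list to pass that test here). Of 23 cDC1 identity genes, 19 were lower and 0 higher, also adjusted over the list alone (median -2.34, camera adjusted p = 2.89e-21; adjusted p = 0.166 with an estimated correlation). C-type lectins had 16 members higher and 6 lower of 23, the same adjusted over the list alone (median 3.86, or 4.35 with genes at their bound; camera adjusted p = 4.61e-13, adjusted p = 0.113 with an estimated correlation). Fc receptors and complement had 15 higher and 2 lower of 20, or 15 and 3 adjusted over the list alone (camera adjusted p = 2.33e-18, adjusted p = 0.099 with an estimated correlation). With leukocyte scaling Fc receptors and complement came to 9 higher and 6 lower (median 2.42, or 1.05 scaled) and C-type lectins to 12 and 8 (median 2.49). The cDC2 identity genes then came to 14 higher and 4 lower (median 1.87) and the cDC1 identity genes to 0 and 23 (median -3.71). The low-affinity IgG receptor Fcgr3 stood at 108 ± 19.8 against 2.60 ± 0.611 CPM. Of 20 NF-kB targets, 15 were higher and 2 lower in both adjustments (camera adjusted p = 1.56e-11, adjusted p = 0.166 with an estimated correlation). Nfkbiz, a nuclear regulator of that pathway, stood at 277 ± 29.6 against 19.5 ± 4.54 CPM. Inflammatory cytokines had 9 higher and 2 lower of 17 in both adjustments (camera adjusted p = 0.029, adjusted p = 0.200 with an estimated correlation). Tnf was higher by 3.06 ± 0.31 and the IL-1 receptor antagonist Il1rn by 5.61 ± 0.62. NF-kB targets came to 12 higher and 5 lower with leukocyte scaling, and inflammatory cytokines to 7 and 4. The call of the cytokine list was lost without CD11b+ healthy library 2 (limma's camera adjusted p = 0.0661; 2.32e-05 to 0.200 over the camera alternatives run for this list).

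Markers of other cell types moved with this comparison. Macrophage markers had 12 higher in CD11b+ cells and 3 lower of 19, the same adjusted over the list alone (camera adjusted p = 7.99e-09, adjusted p = 0.108 with an estimated correlation). The growth factor receptor Csf1r stood at 177 ± 27.3 against 9.91 ± 2.58 CPM and the mannose receptor Mrc1 at 156 ± 13.1 against 1.68 ± 1.31 CPM. All 13 T cell, all 12 NK cell and all 11 B cell markers measured were higher in CD11b+ cells in both adjustments (medians 2.18, 2.53 and 2.75, or 0.81, 1.16 and 1.38 with leukocyte scaling). For these lists camera gave adjusted p = 1.73e-13, 4.85e-08 and 9.65e-08, and adjusted p = 0.141, 0.0687 and 0.0687 with an estimated correlation. Examples were Tcf7, a T cell transcription factor (2.39 ± 0.20), the NK receptor Klrd1 (4.22 ± 0.28) and Cd79b, a chain of the B cell receptor (3.81 ± 0.28). Monocyte markers had 10 of 13 higher and neutrophil markers 7 of 8, with 0 lower and the same counts adjusted over the list alone (camera adjusted p = 4.08e-06 and 2.53e-05, adjusted p = 0.113 and 0.166 with an estimated correlation). With leukocyte scaling monocyte markers came to 4 higher and 1 lower (median 1.44, or 0.07 scaled), macrophage markers to 8 and 4 (median 0.52) and neutrophil markers to 7 and 0. T, NK and B cell markers then had 11, 7 and 8 higher. Csf3r, the receptor of G-CSF, was higher by 5.49 ± 0.54. Of 22 dissociation and stress genes, 15 were higher and 2 lower in both adjustments, with a median of 1.24 that became -0.13 with leukocyte scaling, where 7 were higher and 6 lower (camera adjusted p = 1.04e-08, adjusted p = 0.166 with an estimated correlation). The immediate-early gene Jun stood at 466 ± 94.7 against 84.2 ± 10.5 CPM.

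Tubule markers were lower in CD11b+ cells for 12 of 15 genes, or 13 adjusted over the list alone (camera adjusted p = 5.59e-06, adjusted p = 0.166 with an estimated correlation). The endocytic receptor Cubn was lower by -2.27 ± 0.26. All 7 mitochondrially encoded genes and all 20 oxidative phosphorylation genes were lower in both adjustments (camera adjusted p = 5.01e-09 and 5.94e-09, adjusted p = 0.166 for each with an estimated correlation). The complex I genes mt-Nd4 and Ndufv1 differed by -1.70 ± 0.16 and -1.27 ± 0.16. In all, 7084 genes passed, 3604 higher and 3480 lower in CD11b+ cells; leukocyte scaling changed the split to 648 higher and 10091 lower, and 297 passed in limma with the tubule score as a covariate.

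In inflamed kidneys the same comparison asked how the subsets differ during disease. Mmp12, a macrophage elastase, averaged 798 ± 61.3 CPM in CD11b+ and 4.99 ± 0.174 CPM in CD103+ cells (SD, n = 3 each; log2 difference 7.31 ± 0.24, limma adjusted p = 1.63e-10). Cd14, the coreceptor for lipopolysaccharide, averaged 2241 ± 215 against 84.7 ± 7.40 CPM (4.72 ± 0.30, limma adjusted p = 9.1e-08). Tlr3, the endosomal sensor of double-stranded RNA, was 47.7-fold lower in CD11b+ cells (6.80 ± 0.482 against 327 ± 47.3 CPM, limma adjusted p = 9.02e-10). Rrm2, a subunit of the enzyme that makes deoxynucleotides for DNA replication, was 2.85-fold lower (116 ± 8.91 against 331 ± 10.5 CPM).

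Spic (ENSMUSG00000004359, chromosome 10, 88674772 to 88685015), the transcription factor of iron-recycling macrophages, was 1985-fold higher in CD11b+ cells by reads (95% counting interval 356 to 78430) at 31.4 ± 5.72 CPM. Mmp8, a collagenase of neutrophils, was 1083-fold higher (299 to 8945) and Retnla 1097-fold (196.5 to 43350), while Cxcr2, a chemokine receptor of neutrophils, was at least 311-fold higher because the 3 CD103+ libraries held 0 reads. Adgre4, an adhesion receptor of macrophages, stood at 231 ± 18.5 against 0.434 ± 0.345 CPM. Hp, haptoglobin, which binds free haemoglobin, stood at 64.9 ± 27.0 against 0.113 ± 0.128 CPM and Cd300e, an activating receptor of monocytes, at 85.5 ± 9.59 against 0.220 ± 0.192 CPM. Cd209b was higher by 9.17 ± 0.93 on the log2 scale. Toward CD103+ cells the differences were -9.03 ± 0.73 for Cyp8b1 (ENSMUSG00000050445, chromosome 9, 121914356 to 121916305), a cytochrome of bile acid synthesis, and -8.64 ± 0.46 for the signalling protein Gcsam. Further ones were -8.45 ± 0.91 for the orphan receptor Gpr33, -8.42 ± 0.51 for Cd207, -8.15 ± 0.67 for Gramd2 and -6.84 ± 0.48 for the adaptor Clnk.

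Several lists passed camera and also passed with an estimated correlation. Of 23 cDC1 identity genes, 22 were lower in CD11b+ cells and 0 higher in both adjustments, for all genes and adjusted over the list alone (median -3.62; camera adjusted p = 7.27e-99, adjusted p = 0.026 with an estimated correlation). Of 22 cDC2 identity genes, 14 were higher and 3 lower, or 16 and 3 adjusted over the list alone (median 3.02; 6.55e-30 by camera and adjusted p = 0.0133 with an estimated correlation). Mgl2 reached 2603 ± 240.1 against 16.5 ± 4.99 CPM. Macrophage markers had 15 higher and 1 lower of 19, or 17 and 1 adjusted over the list alone (median 4.68; camera adjusted p = 3.31e-34, adjusted p = 0.00767 with an estimated correlation). Csf1r, whose exons overlap other genes over 15.1%, stood at 458 ± 58.9 against 7.98 ± 1.18 CPM. Monocyte markers had 8 of 13 higher, or 9 adjusted over the list alone (camera adjusted p = 1.59e-06, adjusted p = 0.0467 with an estimated correlation). The matrix protein fibronectin, Fn1, and the peptidase Ace were higher by 7.90 ± 0.54 and 6.12 ± 0.58. Neutrophil markers had 7 of 8 higher in both adjustments (median 7.67; camera adjusted p = 1.07e-13, adjusted p = 0.0456 with an estimated correlation). In CD11b+ cells Csf3r stood at 79.0 ± 14.4 CPM and the alarmin S100a9 at 36.4 ± 22.3 CPM. Summed over the list, neutrophil markers came to 211 ± 64.7 CPM in CD11b+ and 7.55 ± 6.05 CPM in CD103+ cells.

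Fc receptors and complement had 15 of 20 higher in CD11b+ cells and 0 lower, or 17 adjusted over the list alone (median 3.38; camera adjusted p = 7.1e-38, adjusted p = 0.0133 with an estimated correlation). Fcgr3 averaged 525 ± 43.6 against 10.4 ± 0.478 CPM, and C5ar1, the receptor of the complement fragment C5a, 235 ± 65.4 against 0.705 ± 0.602 CPM. C-type lectins had 15 higher and 4 lower of 23, or 16 and 4 adjusted over the list alone (camera adjusted p = 3e-19, adjusted p = 0.0246 with an estimated correlation). Clec4a3 was higher by 7.90 ± 0.36 and the fatty acid receptor Cd36 lower by -2.82 ± 0.14. Matrix, protease and repair genes had 9 higher and 1 lower of 19, or 10 and 1 adjusted over the list alone (median 2.15; camera adjusted p = 1.38e-10, adjusted p = 0.0425 with an estimated correlation). Thrombospondin, Thbs1, was higher by 4.83 ± 0.43. Of 18 genes that support regulatory T cells, 6 were higher and 1 lower, or 7 and 1 adjusted over the list alone (median 1.12; camera adjusted p = 0.0165, adjusted p = 0.0375 with an estimated correlation). Within that list Cd274, the checkpoint ligand PD-L1, was higher in CD11b+ cells (1.13 ± 0.21). Ido1, which breaks down tryptophan, was lower (29.0-fold by reads, 95% counting interval 9.55 to 143, at 1.30 ± 0.665 CPM in CD103+ cells). Of 26 cell cycle genes, 21 were lower in CD11b+ cells and 0 higher, or 25 lower adjusted over the list alone (median -1.10; camera adjusted p = 9.92e-11, adjusted p = 0.0279 with an estimated correlation). The mitotic kinase Cdk1 differed by -1.48 ± 0.24.

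Other lists passed camera alone. Chemokines had 9 higher and 0 lower of 17, or 10 adjusted over the list alone (camera adjusted p = 1.98e-07, adjusted p = 0.146 with an estimated correlation). The monocyte attractant Ccl9 was higher by 6.17 ± 0.24 and the neutrophil attractant Cxcl2 by 6.83 ± 0.67. NF-kB targets had 12 of 20 higher and 0 lower in both adjustments (camera adjusted p = 8.65e-07, adjusted p = 0.175 with an estimated correlation). Ptgs2, the inducible cyclooxygenase, was higher by 3.78 ± 0.39 and Nfkbiz by 2.48 ± 0.18. Dissociation and stress genes had 7 higher and 1 lower of 22, or 8 and 2 adjusted over the list alone (median 0.39; camera adjusted p = 0.00564, adjusted p = 0.396 with an estimated correlation). Costimulation and checkpoint ligands had 7 higher and 2 lower of 15, or 10 and 4 adjusted over the list alone (camera adjusted p = 0.0494, adjusted p = 0.290 with an estimated correlation). The costimulation call was lost without CD103+ healthy library 2, CD11b+ healthy library 1 or 3, CD103+ inflamed library 2 or 3, or CD11b+ inflamed library 1 or 2 (limma's camera adjusted p = 0.0573 to 0.127). It was also lost with a replicate block (camera adjusted p = 0.058) and with leukocyte scaling (0.0696). Over the camera alternatives run for this list, adjusted p ran from 0.00578 to 0.290. Tubule markers did not differ detectably in this comparison (median 0.23, 0 of 15 past the threshold in either adjustment, camera adjusted p = 0.522, adjusted p = 0.739 with an estimated correlation). Neither did T cell markers (median 0.18, 0 of 13, camera adjusted p = 0.580). In all, 2534 genes passed, 1370 higher and 1164 lower in CD11b+ cells, and 4472 passed with array weights and 4062 with only the groups compared. The share that was higher, 54.1%, fell to 43.3% with median-centred libraries (1188 higher, 1553 lower) and was 47.6% with leukocyte scaling (804 and 886).

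**Figure D3:**
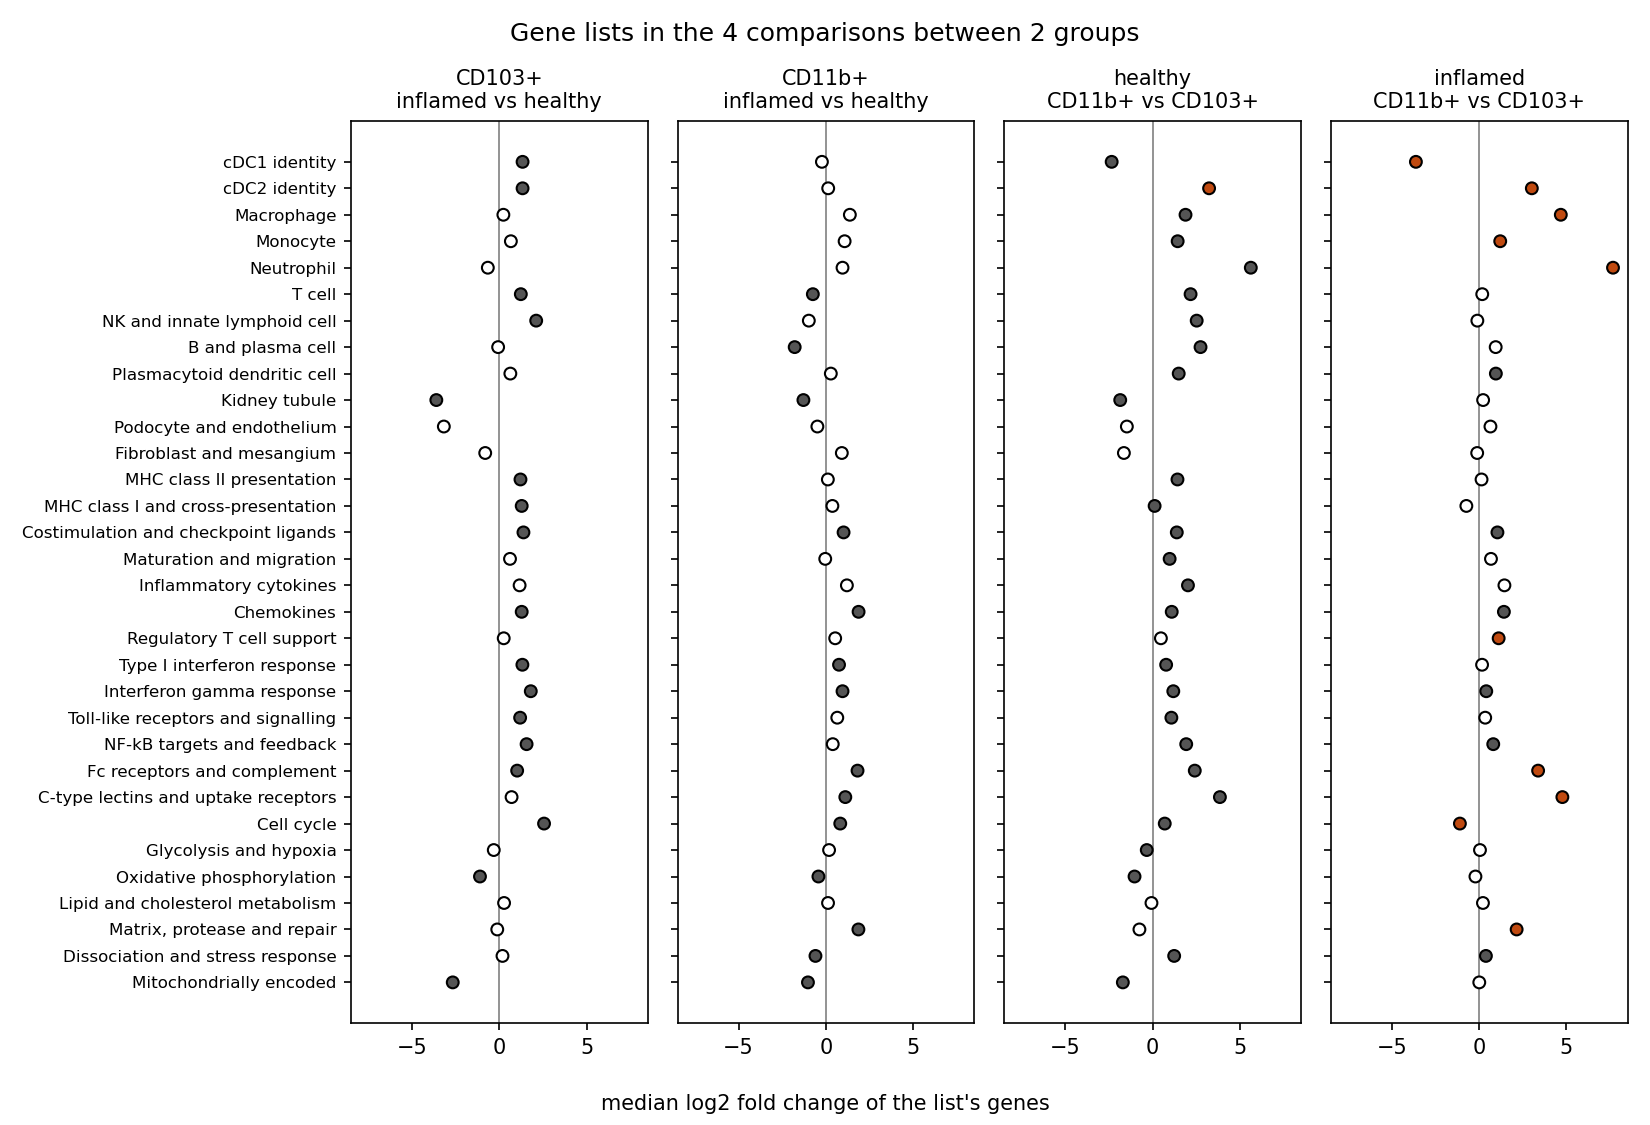
Median log2 change of the genes of 32 lists in the 4 comparisons between 2 groups. Orange points pass limma's camera with an estimated correlation as well, dark points pass camera with its preset correlation alone, and white points do not pass; the cDC1 median is -3.62 and the macrophage median 4.68 between the inflamed subsets, and in CD103+ cells the cDC1 median in nephritis is 1.33, or -0.25 with leukocyte scaling.

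In CD103+ cells the comparison of nephritis with health asked how the cDC1-type subset responds to the disease. Ccl1 (ENSMUSG00000020702, chromosome 11, 82176657 to 82305690), a chemokine that attracts T cells through CCR8, rose from 0.142 ± 0.195 to 62.5 ± 18.6 CPM (SD, n = 3 each; log2 change 9.17 ± 0.79, limma adjusted p = 5.71e-07). Csf2, the growth factor GM-CSF, rose from 0.437 ± 0.456 to 13.8 ± 4.33 CPM, and the inhibitory receptor Klrb1b from 2.51 ± 0.286 to 47.3 ± 2.69 CPM. The replication helicase subunit Mcm5 rose from 23.0 ± 3.45 to 197 ± 22.7 CPM (3.10 ± 0.15, limma adjusted p = 2.98e-08). Cxcl9, an interferon-induced chemokine for T cells, rose from 13.8 ± 3.55 to 150.4 ± 31.2 CPM.

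The other genes with the largest rises belonged to replication, repair and division: Rad54b, a recombination helicase (to 23.4 ± 2.31 CPM), Kntc1, a kinetochore protein (4.14 ± 0.56), and Dtl, which marks replication proteins for destruction (4.14 ± 0.32). So did Stil, a centriole protein (4.05 ± 0.35), and Cdc6, which loads the replication helicase (3.99 ± 0.45). Exons of Rad54b, Klrb1b and Csf2 overlap other genes over 35.9%, 26.9% and 12.0%. All 26 cell cycle genes rose, also adjusted over the list alone, with a median of 2.56 that stayed at 0.98 with leukocyte scaling, where 20 of 26 were still higher (camera adjusted p = 1.86e-23, adjusted p = 0.107 with an estimated correlation). Birc5, survivin, a regulator of chromosome segregation, rose from 10.2 ± 0.506 to 62.6 ± 9.85 CPM. All 18 interferon gamma genes rose in both adjustments, with a median of 1.80 and of 0.22 with leukocyte scaling (camera adjusted p = 1.53e-08, adjusted p = 0.0989 with an estimated correlation). With that scaling 5 were higher. The GTPase Gbp4 rose by 2.82 ± 0.19. NK cell markers rose for 11 of 12 genes in both adjustments (median 2.11, 0.53 with leukocyte scaling; camera adjusted p = 0.000869, adjusted p = 0.325 with an estimated correlation). With leukocyte scaling 2 were higher and 1 lower. Klrb1c, the NK1.1 antigen, rose by 3.80 ± 0.34. Summed NK cell markers rose from 89.6 ± 20.6 to 290 ± 26.0 CPM and summed T cell markers from 241 ± 61.6 to 606 ± 58.7 CPM. Whether lymphocytes in the samples were a source of Ccl1, Csf2 or other genes that rose was not tested. All 13 T cell markers rose in both adjustments (median 1.23, or -0.35 with leukocyte scaling, where 1 was higher and 4 lower; camera adjusted p = 0.00108, adjusted p = 0.383 with an estimated correlation).

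The leukocyte level of the samples rose by 1.58 on the log2 scale, and the medians of the other immune lists named here changed sign with leukocyte scaling. cDC1 identity genes rose for 20 of 23 in both adjustments with a median of 1.33, or -0.25 with leukocyte scaling (camera adjusted p = 0.000157, adjusted p = 0.383 with an estimated correlation). With leukocyte scaling 4 were higher and 7 lower. Among them Itgae rose by 3.55 ± 0.28, or 1.97 with that scaling, and Xcr1 by 1.76 ± 0.28, or 0.18. Clec9a (1.18 ± 0.30), Irf8 (0.75 ± 0.24), Batf3 (0.80 ± 0.25), Zbtb46 (1.22 ± 0.31) and Flt3 (from 152 ± 67.7 to 284 ± 6.43 CPM) rose in limma. They turned to -0.40, -0.83, -0.77, -0.35 and -0.57 with leukocyte scaling. CD103+ healthy library 2 carried much of these rises: without it Batf3 (0.50) no longer passed, and Irf8, Zbtb46 and Flt3 came to 0.36, 0.81 and 0.63. The Irf8 call was also lost with quantile normalization (0.50) and when only the groups compared were fitted. Sirpa fell by 1.41 ± 0.25 on the log2 scale, to 6.39 ± 2.07 CPM. The cDC2 identity genes rose for 16 of 22 and fell for 3 in both adjustments (median 1.33, -0.25 with leukocyte scaling; camera adjusted p = 0.00254, adjusted p = 0.325 with an estimated correlation). With leukocyte scaling 1 was higher and 6 lower. Kit, the stem cell factor receptor, rose by 2.27 ± 0.14. Costimulation and checkpoint ligands rose for 12 of 15 and fell for 1, or 13 and 1 adjusted over the list alone (median 1.38, or 1.47 with genes at their bound, and -0.20 with leukocyte scaling; camera adjusted p = 0.00198, adjusted p = 0.336 with an estimated correlation). With leukocyte scaling 2 were higher and 3 lower. Cd274 rose by 2.53 ± 0.21, or 0.96 with that scaling. MHC class I genes rose for 15 of 19 and fell for 1, MHC class II genes for 12 of 14 and 1, and NF-kB targets for 17 of 20 and 3, the same adjusted over the list alone. Their medians of 1.28, 1.21 and 1.56 became -0.30, -0.37 and -0.02 with leukocyte scaling (camera adjusted p = 0.000363, 0.00409 and 0.00108, adjusted p = 0.383, 0.487 and 0.383 with an estimated correlation). The calls of both MHC lists were lost with leukocyte scaling (limma's camera adjusted p = 0.0612 and 0.314; 1.45e-06 to 0.383 and 1.08e-06 to 0.487 over the camera alternatives), where each had 0 higher and 8 lower, and NF-kB targets had 2 higher and 6 lower. Il10, an anti-inflammatory cytokine, rose by 6.17 ± 0.73 from 0.104 ± 0.143 to 6.30 ± 1.92 CPM, and Tnfaip3, the NF-kB inhibitor A20, by 2.16 ± 0.18.

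Among the largest falls, Slc22a7, an organic anion transporter of the tubule, fell at least 360-fold, from 17.6 ± 6.79 CPM to 0 reads in the 3 inflamed libraries. Ttc36 fell by 8.22 ± 0.42 on the log2 scale, Emcn, a sialomucin of endothelium, by 7.83 ± 1.20 and Aspg, an asparaginase, by 7.12 ± 1.36. Hpd, an enzyme of tyrosine breakdown, fell by 6.33 ± 0.46, Acsm3, which activates fatty acids, by 6.29 ± 0.61 and the calcium-binding Calb1 of the distal tubule by 6.13 ± 0.97. The cytochrome Cyp2d9 changed by -6.53 ± 0.58. Tubule markers fell for 14 of 15 in both adjustments (median -3.61; camera adjusted p = 3.39e-11, adjusted p = 0.325 with an estimated correlation). Kap, an androgen-regulated proximal tubule gene, and the receptor megalin, Lrp2, fell by 4.96 ± 0.30 and 3.37 ± 0.28 on the log2 scale. All 7 mitochondrially encoded genes and 19 of 20 oxidative phosphorylation genes fell in both adjustments (medians -2.67 and -1.11; camera adjusted p = 2.56e-13 and 9.29e-09, adjusted p = 0.336 and 0.383 with an estimated correlation). The changes of mt-Nd4, Cyc1 of complex III and Cox5a of complex IV were -3.00 ± 0.16, -2.89 ± 0.20 and -4.51 ± 0.23. Macrophage markers went both ways, 5 higher and 6 lower of 19 in both adjustments, with a median of 0.23 (-1.35 with leukocyte scaling), a mean of -0.31 and a camera direction of down (adjusted p = 0.268, adjusted p = 0.676 with an estimated correlation). The dead-cell receptor Mertk fell by 2.92 ± 0.34 on the log2 scale. In all, 8851 genes passed, 4911 higher and 3940 lower; with leukocyte scaling 376 were higher and 9982 lower. With the tubule score as a covariate limma called 0 genes, with 1295 at an unadjusted p under 0.05, and the median SE rose from 0.263 to 0.987.

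In CD11b+ cells the same comparison asked how the other subset responds to the disease. Summed macrophage markers rose from 3810 ± 275 to 8301 ± 562 CPM in these samples. A changed mix of sorted cells and a response within cells cannot be told apart here. Fcgr3 rose from 108 ± 19.8 to 525 ± 43.6 CPM (SD, n = 3 each; log2 change 2.29 ± 0.18, limma adjusted p = 2.68e-06). Tgfbi, a matrix protein induced by TGF-beta, rose 12.6-fold from 61.9 ± 14.2 to 771 ± 100.0 CPM (3.66 ± 0.27, limma adjusted p = 1.62e-06). Clec4n, the Dectin-2 receptor for fungal sugars, rose from 9.17 ± 1.28 to 309 ± 34.0 CPM, and Flrt3 (ENSMUSG00000051379, chromosome 2, 140650914 to 140671469), an adhesion protein, from 0.602 ± 0.769 to 74.7 ± 6.04 CPM. The immediate-early gene Jun fell from 466 ± 94.7 to 87.3 ± 10.4 CPM.

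Among the largest rises were Ccl12, a monocyte attractant, by 7.22 ± 0.90, and the neutrophil attractant Cxcl1, by 5.98 ± 0.82. Cxcl9 and Cxcl2, members of the chemokine list, rose by 3.68 ± 0.21 and 3.75 ± 0.67. The interferon-induced GTPase Iigp1 rose by 6.86 ± 1.12, and Stab1, a scavenger receptor, by 5.29 ± 0.77, while Ffar2, a receptor for short-chain fatty acids, rose from 0.563 ± 0.692 to 14.1 ± 5.31 CPM. Vcam1, an adhesion molecule, rose by 5.15 ± 1.28 with a wide spread (37.1 ± 31.9 CPM in inflamed libraries), and its call was lost in limma-voom (5.12). Timp1, an inhibitor of metalloproteinases, rose 378-fold by reads (95% counting interval 67.5 to 14950), and Il23a, the p19 chain of IL-23, rose at least 35.3-fold, from 0 reads to 2.01 ± 1.57 CPM. Chemokines rose for 11 of 17 and fell for 1, or 13 and 1 adjusted over the list alone (camera adjusted p = 3.35e-05, adjusted p = 0.370 with an estimated correlation). Fc receptors and complement rose for 15 of 20 and fell for 0, or 16 adjusted over the list alone (camera adjusted p = 9.05e-08, adjusted p = 0.140 with an estimated correlation). The complement receptor C3ar1 rose by 3.94 ± 0.65. Matrix, protease and repair genes rose for 10 of 19 and fell for 1 in both adjustments (median 1.86; camera adjusted p = 7.19e-06, adjusted p = 0.269 with an estimated correlation). With leukocyte scaling chemokines came to 7 higher and 1 lower, Fc receptors and complement to 11 and 0 and matrix genes to 9 and 1.

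Interferon gamma genes rose for 13 of 18 and fell for 1, or 14 and 1 adjusted over the list alone (camera adjusted p = 5.14e-09, adjusted p = 0.131 with an estimated correlation). The GTPase Gbp3 rose by 2.60 ± 0.24. Cell cycle genes rose for 17 of 26 and fell for 1 in both adjustments (median 0.82; camera adjusted p = 1.44e-07, adjusted p = 0.269 with an estimated correlation). With leukocyte scaling interferon gamma genes came to 6 higher and 1 lower and cell cycle genes to 10 and 1. Mcm4 rose from 57.7 ± 8.23 to 198 ± 15.1 CPM. Costimulation and checkpoint ligands rose for 9 of 15 and fell for 0, or 9 and 1 adjusted over the list alone (camera adjusted p = 0.00332, adjusted p = 0.370 with an estimated correlation). Cd274 rose by 1.94 ± 0.21 and the costimulator Cd86 by 1.29 ± 0.23. C-type lectins and uptake receptors rose for 11 of 23 and fell for 4 in both adjustments (camera adjusted p = 0.0345, adjusted p = 0.370 with an estimated correlation). The scavenger receptor Msr1 rose by 4.46 ± 0.69 and the dead-cell receptor Axl by 2.84 ± 0.32. The call of the lectin list was lost without CD103+ healthy library 3, CD11b+ healthy library 3, or CD11b+ inflamed library 1 or 3 (limma's camera adjusted p = 0.0542 to 0.0708; 0.00392 to 0.370 over the camera alternatives run for this list). Macrophage markers rose for 13 of 19 and fell for 4, or 13 and 5 adjusted over the list alone (median 1.37; camera adjusted p = 0.0543, adjusted p = 0.370 with an estimated correlation). With leukocyte scaling macrophage markers came to 9 higher and 4 lower, costimulation and checkpoint ligands to 7 and 0 and C-type lectins to 6 and 4. The complement gene C1qc rose by 3.45 ± 0.57. Camera passed the macrophage list without CD103+ healthy library 1, 2 or 3, CD11b+ healthy library 2, CD103+ inflamed library 1, 2 or 3, or CD11b+ inflamed library 1 (limma's camera adjusted p = 0.00955 to 0.0342; 0.000764 to 0.370 over the camera alternatives).

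Other lists fell in CD11b+ samples. B cell markers fell for 8 of 11 and T cell markers for 8 of 13, with 0 higher in both adjustments (camera adjusted p = 2.13e-06 and 0.00168, adjusted p = 0.140 and 0.385 with an estimated correlation). Ebf1, a B cell transcription factor, Cd79a, a B cell receptor chain, and the T cell adaptor Lat fell by 3.16 ± 0.34, 1.79 ± 0.25 and 1.67 ± 0.28 on the log2 scale. Gimap1, a GTPase of lymphocytes, fell by 3.45 ± 0.38. Of 22 dissociation and stress genes, 12 fell and 1 rose, or 14 and 2 adjusted over the list alone (median -0.60; camera adjusted p = 2.7e-05, adjusted p = 0.370 with an estimated correlation). The immediate-early genes Ier2 and Junb changed by -3.31 ± 0.26 and -2.63 ± 0.28. Tubule markers fell for 9 of 15, or 10 adjusted over the list alone (median -1.29; camera adjusted p = 4.11e-05, adjusted p = 0.370 with an estimated correlation). Kap and the tubule transporters Slco1a1 and Slc7a13 fell by 3.55 ± 0.30, 3.45 ± 0.73 and 3.30 ± 0.48, and Ttc36 and Acsm3 by 7.36 ± 0.42 and 3.45 ± 0.61. Mitochondrially encoded genes fell for 6 of 7 in both adjustments, and oxidative phosphorylation genes fell for 8 of 20 and rose for 1, or 9 and 1 adjusted over the list alone (camera adjusted p = 2.7e-05 and 0.000249, adjusted p = 0.370 and 0.606 with an estimated correlation). The list medians were -1.03 and -0.43. The changes of mt-Nd6 of complex I, Cox5a and Cyc1 were -1.39 ± 0.17, -4.85 ± 0.23 and -2.32 ± 0.20, so Cox5a and Cyc1 lay far below the median of their list. Exons of Ttc36, Acsm3, Gimap1 and Cox5a overlap other genes over 47.6%, 39.8%, 36.0% and 12.8%.

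Identity genes moved in both directions in CD11b+ cells. Itgam rose by 1.34 ± 0.15 and Sirpa by 0.94 ± 0.25, the latter not passing with leukocyte scaling (0.60) or quantile normalization (0.61). Flt3 fell by 1.34 ± 0.25, Batf3 by 1.25 ± 0.25 and Xcr1 by 2.04 ± 0.28 on the log2 scale. Itgae rose by 1.17 ± 0.28 and Clec9a fell by 1.12 ± 0.30 on the log2 scale. Both calls were lost with a pseudocount of 4 CPM (0.51 and -0.68) and in limma-voom (1.10 and -1.07), and that of Itgae also with the tubule covariate (0.54). Batf3 no longer passed once the trend on GC content and length was removed (-0.34). Irf4, Irf8 and Zbtb46 did not pass (-0.30 ± 0.26, -0.42 ± 0.24 and -0.27 ± 0.31). Irf8 passed, however, without CD103+ healthy library 2 (-0.42), with array weights (-0.47), with only the groups compared and with leukocyte scaling (-0.76). In all, 5087 genes passed, 2850 higher and 2237 lower; with leukocyte scaling 3141 passed, 727 higher and 2414 lower, and with the tubule score as a covariate 1772 passed.

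Changes in nephritis were partly shared between the subsets. Genes that rose in both numbered 2071, where 987 would be shared by independent lists, and genes that fell in both numbered 1317 against 622. Both subsets came from the same 6 mice, so the number for independent lists is not a value for no shared change. Another 187 rose in CD103+ and fell in CD11b+ cells, or the reverse for 157. Across genes, which are not independent replicates, the log2 changes correlated with Pearson's r = 0.49 and Spearman's rho = 0.49. Between the subset differences of healthy and inflamed kidneys, 809 genes were higher in CD11b+ cells in both states against 348 for independent lists. Another 395 were lower in both against 286, while 204 were higher in healthy and lower in inflamed kidneys and 178 the reverse, with r = 0.38 and rho = 0.08 across genes. With leukocyte scaling the genes shared by both responses came to 158 higher and 2213 lower, against 19 and 1699 for independent lists.

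The last comparison tested whether nephritis changed the subsets differently, as the change in CD11b+ cells minus that in CD103+ cells, and 5022 genes passed. Toward CD11b+ cells, Thbs1, an activator of TGF-beta, went from 7.95 ± 1.05 to 62.6 ± 8.73 CPM in CD11b+ cells and from 11.5 ± 6.07 to 2.53 ± 1.81 CPM in CD103+ cells (n = 3 per group; difference of log2 changes 5.23 ± 0.60, limma adjusted p = 0.000194). Tgm2, a cross-linking enzyme with an exon overlap of 21.8%, differed by 4.15 ± 0.37. In the other direction Csf2 stayed near 1.13 ± 0.776 and 1.24 ± 0.981 CPM in CD11b+ cells while it rose in CD103+ cells (-5.92 ± 1.56, limma adjusted p = 0.0109). Xcl1, the ligand of XCR1, went from 8.37 ± 2.92 to 2.63 ± 0.816 and from 1.64 ± 0.958 to 14.8 ± 5.03 CPM (-4.91 ± 0.63; exon overlap 18.7%).

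Cell cycle genes changed less in CD11b+ than in CD103+ cells for 24 of 26, or 25 adjusted over the list alone (median difference -1.82, or -0.58 and 4 of 26 with leukocyte scaling; camera adjusted p = 9.62e-16, adjusted p = 0.0963 with an estimated correlation). NK and T cell markers differed in the same direction for 12 of 12 and 13 of 13 in both adjustments (medians -2.77 and -1.96, or -1.53 and -0.73 with leukocyte scaling; camera adjusted p = 2.62e-09 and 1.29e-11, adjusted p = 0.0963 and 0.230 with an estimated correlation). With leukocyte scaling 8 of 12 NK and 2 of 13 T cell markers differed. The cytotoxic pore protein Prf1 and the T cell costimulator Cd28 differed by -3.14 ± 0.54 and -2.13 ± 0.27. Matrix, protease and repair genes differed toward CD11b+ cells for 12 of 19 and against them for 0, or 12 and 1 adjusted over the list alone (median 2.77; camera adjusted p = 1.15e-05, adjusted p = 0.210 with an estimated correlation). Macrophage markers differed for 12 of 19 and 1, or 13 and 2 adjusted over the list alone (median 1.38; camera adjusted p = 0.00192, adjusted p = 0.230 with an estimated correlation). Tubule markers differed for 13 of 15 in both adjustments (median 2.19; camera adjusted p = 6.71e-07, adjusted p = 0.283 with an estimated correlation), as the tubule share fell more in CD103+ samples. Of the genes that passed, 2510 differed toward CD11b+ cells and 2512 toward CD103+ cells. With leukocyte scaling the split was 6532 and 166, and limma with the tubule score as a covariate called 0, with 1244 at an unadjusted p under 0.05.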

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

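The results of this part are those of the difference between the responses of the subsets to nephritis, picked out because the groups differed in how they responded. The tests of the ratio of tubule markers, of depth, of leukocyte scaling, of matched short transcripts and of genomic DNA were chosen only after the result was seen.

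In this comparison 5022 genes passed. Large differences toward CD11b+ cells were in Rnase1, a secreted ribonuclease (6.91 ± 1.56), the transporter Abcc3 (6.75 ± 1.46), Flrt3 (6.58, limma adjusted p = 0.000894), Stab1 (6.09, limma adjusted p = 0.00127) and the coagulation factor F10 (5.80 ± 0.99). The response of Rnase1 rested on its fall in CD103+ cells, from 11.6 ± 7.39 to 0.463 ± 0.727 CPM, against 1.04 ± 0.503 to 2.07 ± 0.701 CPM in CD11b+ cells. The largest toward CD103+ cells were in Csf2 (-5.92 ± 1.56), Xcl1 (-4.91 ± 0.63), Emilin2 (-4.80 ± 0.82), Cyp8b1 (-4.76 ± 1.04), Gcsam (-4.35 ± 0.66) and Gpr33 (-4.25 ± 1.29). The Gpr33 call was lost in limma without CD103+ healthy library 2 (-3.78), CD11b+ healthy library 2 (-3.80) or CD103+ inflamed library 1 (-4.05), with leukocyte scaling (-3.02) and in limma-voom (-4.55). With a pseudocount of 4 CPM the differences of Emilin2 and Cyp8b1 came to -0.04 and -0.44. Among list members, Thbs1 (5.23), Tgm2 (4.15), Csf1r (1.66) and Cubn (2.36) differed toward CD11b+ cells and Prf1 (-3.14), Cd28 (-2.13) and the replication gene Mcm6 (-2.89) toward CD103+ cells. Il23a (6.52) had 0 or 1 reads in 3 of the groups, so its value depends on the offset, and its call was lost without CD11b+ inflamed library 3 (5.93).

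Of the identity genes, Sirpa differed toward CD11b+ cells (2.35 ± 0.35) and Itgae (-2.38 ± 0.40), Xcr1 (-3.79 ± 0.39), Clec9a (-2.30 ± 0.43), Irf8 (-1.17 ± 0.35), Batf3 (-2.06 ± 0.35), Irf4 (-2.50 ± 0.37), Zbtb46 (-1.49 ± 0.43) and Flt3 (-2.34 ± 0.36) toward CD103+ cells. Itgam (-0.62 ± 0.21) lost its call without any of 7 libraries: CD11b+ healthy 2 or 3, CD103+ inflamed 1, 2 or 3, or CD11b+ inflamed 1 or 3 (-0.58 to -0.65). Its call was also lost with a pseudocount of 0.25 CPM (-0.50) or 4 CPM (0.39), with no filter, with a replicate block, in limma-voom and with the tubule covariate (-0.90). With leukocyte scaling Itgam came to 0.61, Irf8 to 0.07 and Zbtb46 to -0.26, which did not pass.

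The list medians were 1.38 for macrophage markers, 2.19 for tubule markers, 0.50 for glycolysis, 0.83 for oxidative phosphorylation, 2.77 for matrix genes and 1.65 for mitochondrially encoded genes. None of these passed camera with an estimated correlation (adjusted p = 0.230, 0.283, 0.327, 0.363, 0.210 and 0.290 with an estimated correlation, in the same order). On the other side they were -1.49 for cDC1 identity, -0.96 for cDC2 identity, -1.96 for T cell, -2.77 for NK cell and -1.70 for B cell markers, -1.33 for MHC class II, -1.01 for MHC class I, -0.89 for maturation, -0.61 for interferon gamma, -1.18 for NF-kB, -1.82 for cell cycle and -1.05 for stress genes. None of these passed camera with an estimated correlation either (adjusted p = 0.327, 0.234, 0.230, 0.0963, 0.210, 0.448, 0.338, 0.511, 0.290, 0.464, 0.0963 and 0.338 with an estimated correlation, in the same order). Leukocyte scaling took MHC class II from 10 lower to 0 lower (median -0.10), cDC1 identity to 10 lower and 5 higher (median -0.26) and B cell markers to 1 lower (median -0.47). With leukocyte scaling the medians of cDC2 identity, MHC class I, maturation, interferon gamma, NF-kB and stress genes came to 0.27, 0.22, 0.35, 0.63, 0.05 and 0.19. Those of macrophage, tubule, glycolysis, oxidative phosphorylation, matrix and mitochondrially encoded genes came to 2.61, 3.42, 1.74, 2.06, 4 and 2.88. By limma's camera the call of the interferon gamma list was lost without CD11b+ healthy library 2 (adjusted p = 0.0651, and 0.0176 to 0.290 over the camera alternatives). The maturation call was lost without CD103+ healthy library 1 or 2, CD11b+ healthy library 2, CD103+ inflamed library 3 or CD11b+ inflamed library 2 (limma's camera adjusted p = 0.0525 to 0.0829, and 0.00164 to 0.511 over the camera alternatives). The glycolysis call was lost without CD103+ healthy library 1, CD11b+ healthy library 2, CD103+ inflamed library 1 or 3 or CD11b+ inflamed library 3 (limma's camera adjusted p = 0.0531 to 0.061, and 0.0233 to 0.327 over the camera alternatives). With leukocyte scaling the calls of interferon gamma (camera adjusted p = 0.0877), maturation (0.0752) and MHC class I (0.0563) were lost. With a replicate block those of maturation (camera adjusted p = 0.0502) and glycolysis (0.0738) were lost. The number of calls was also compared over 100 splits of the samples: 3 of them, the real one included, gave as many calls, and the highest other gave 5649. Both other splits that gave as many kept the conditions of all 6 CD103+ libraries and of 2 of the 6 CD11b+ libraries, and the highest of the 83 splits that mixed both subsets gave 0. Such splits break up the effect of nephritis within each subset as well as its difference between them. They therefore cannot decide whether the subsets responded differently.

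Kidney tubule genes were highest in healthy CD103+ samples. If RNA of tubule cells in the samples is the source, its genes should keep 1 ratio, and the SD of the differences of 15 markers was 0.48 against a median of 0.61 in 10000 random lists, at percentile 11.2. This lay between the bounds set for the test. The random lists held other genes called lower in the same comparison, which may share that source. The test therefore could not decide, and the source remains open. A difference in depth is excluded, since the ratio of mean read totals was 1.06 while the ratio of tubule shares was 3.45.

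Dendritic cell and proliferation genes rose in CD103+ samples, for which dilution of leukocyte RNA in the healthy samples and a response of the cells may each account. Within groups the tubule and leukocyte scores had r = -0.52 over 12 libraries (exact permutation p = 0.0741 of 1296 permutations), which did not reach the bound set before the test and leaves library-by-library dilution open. Spearman's rho was -0.62 (exact permutation p = 0.108), and r was -0.67 without CD11b+ healthy library 3 and CD11b+ inflamed library 3. After leukocyte scaling the cDC1 median was -0.25 with 4 genes higher, Itgae among them (1.97), and 7 lower, so dilution of those genes stays open. The cell cycle median stayed at 0.98 with 20 of 26 genes higher. If the 39 leukocyte genes measure dilution, it was therefore not the whole cause of that rise. Whether those 39 genes themselves respond to nephritis was not tested. Any difference in handling between healthy and inflamed mice could not be told apart from disease and remains open.

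Of 443 processed pseudogenes, 196 were lower and 47 higher in nephritis in CD103+ samples (median -1.11), and 214 were lower and 12 higher in CD11b+ samples (median -1.39). Pseudogenes lay below their parents by -1.45 in CD11b+ samples (58 of 68 pairs) and -1.04 in CD103+ samples (55 of 68). A constant share of parent reads counted at pseudogenes is therefore excluded as the whole cause. A share that differed between healthy and inflamed libraries was not tested. Loss of short transcripts is excluded as the whole cause in CD11b+ samples, where matched coding genes had a median of -0.51 (-0.79 to -0.25). Since those genes fell too, it may account for a part there. In CD103+ samples the matched median was -0.81 (-1.04 to -0.55). The pseudogene median of -1.11 was within the bound set for the test but below that range. Loss of short transcripts was thus not excluded there, although the pseudogenes fell more than the matched genes. A fall from genomic DNA in healthy samples was not seen in 567 non-coding genes (medians -0.08 in CD11b+ and 0.44 in CD103+ samples). These genes passed the expression filter and can change on their own, so a small DNA signal is not excluded. A biological change and a difference in handling between healthy and inflamed mice remain open because they were not tested.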

How the results depend on the processing

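The alternatives of leukocyte scaling, tubule covariate, limma-voom, coding genes only and GC trend were tests chosen only after the result was seen. Of 240 named-gene results, 240 kept direction and call with median-centred libraries, 237 with quantile normalization, 235 with limma-voom, 218 with leukocyte scaling and 129 with the tubule covariate. Of 160 list results, 79 kept their status with an estimated correlation and 81 lost their call. With leukocyte scaling 134 kept their status, 8 lost their call, 15 gained one and 3 turned direction. A gene or list result that passed in neither setting was counted as kept. Depth limits genes under about 3 reads, and 3 libraries per group limit small changes.

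In limma with the tubule covariate, 0 genes passed for CD103+ cells in nephritis (1295 at an unadjusted p under 0.05) and 0 for the difference of responses (1244 unadjusted), 1772 for CD11b+ cells and 297 between the healthy subsets; the median SE rose from 0.263 to 0.987 in the first, as the covariate follows the groups. Leukocyte scaling gave 3141 calls for CD11b+ cells in nephritis and 10739 between the healthy subsets. Between the inflamed subsets array weights gave 4472 and only the groups compared gave 4062, and the cause was not tested. Genes shared by both responses came to 158 higher and 2213 lower with leukocyte scaling (19 and 1699 for independent lists). At adjusted p under 0.01 they came to 1278 and 736 (487 and 280 for independent lists). Genes shared by both subset differences came to 366 higher and 759 lower with leukocyte scaling (37 and 631 for independent lists). At adjusted p under 0.01 they came to 243 lower (113 for independent lists).

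Signs turned as follows, and the cause was not tested. With the tubule covariate, in CD103+ cells: Xcr1 -0.03, Clec9a -0.46, Irf8 -0.86, Batf3 -0.72, Zbtb46 -0.51, Flt3 -0.13, Mertk 0.25, Kdr 0.32, Pdgfrb 0.57. With leukocyte scaling, in CD103+ cells: Clec9a -0.40, Irf8 -0.83, Batf3 -0.77, Zbtb46 -0.35, Flt3 -0.57, Ifi30 -0.04, Stat2 -0.10; between the healthy subsets, Zbtb46 -1.26; in the difference of responses, Itgam 0.61 and Irf8 0.07. Itgam was 0.39 there with a pseudocount of 4 CPM. Some lists turned their direction in limma's camera with leukocyte scaling and passed it with or without the scaling. They were stress genes in CD103+ cells (adjusted p = 0.048), MHC class II in CD11b+ cells (0.0492) and MHC class I between the healthy subsets (0.485, or 0.0342 unscaled). Unscaled, camera with an estimated correlation gave them adjusted p = 0.994, 0.944 and 0.597. The MHC class I call was also lost in camera with a replicate block (adjusted p = 0.069) and without CD103+ healthy library 1 (0.0569) or 2 (0.209). Medians of other lists changed sign too, as given above.

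Leaving out 1 library at a time gave 7972 to 9188 calls for CD103+ cells in nephritis, 3590 to 5589 for CD11b+ cells, 5850 to 7303 between the healthy subsets, 1840 to 2886 between the inflamed subsets and 4015 to 5938 for the difference of responses. Genes shared by both responses ran from 1536 to 2243 higher and 965 to 1340 lower, and those shared by both subset differences from 652 to 889 and 313 to 438.

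With a replicate block the calls came to 8737, 4843, 6538, 2089 and 4178 in the order above. For inflamed against healthy cells, the block joined healthy and inflamed libraries of the same number, which came from different mice. For the other comparisons it joined libraries of the same number and condition. Libraries that share a number correlated by -0.10, -0.13 and -0.40 in healthy and 0.15, 0.01 and 0.25 in inflamed kidneys. The best correlation with another number was 0.15, 0.32 and 0.27 in healthy and 0.15, 0.02 and -0.16 in inflamed kidneys. The shared number was the best match for inflamed libraries 1 and 3 only. With 3 libraries per group this check could not decide whether a number marks the mouse, and the main fit used no pairing.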

Other observations

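Of the tests quoted in this part, leukocyte scaling was chosen only after the result was seen. Between the inflamed subsets, antigen presentation and innate sensing held genes of both directions. Cybb, the catalytic chain of the NADPH oxidase, was higher in CD11b+ cells (1078 ± 171 against 27.0 ± 4.76 CPM, n = 3 each), while the immunoproteasome subunit Psmb9 (-1.54 ± 0.18), the proteasome activator Psme1 (-1.18 ± 0.18) and the chaperone Pdia3 (-1.73 ± 0.22) were lower. The MHC class I list had 2 higher and 10 lower of 19, also adjusted over the list alone (limma's camera adjusted p = 0.0615), and it passed without CD103+ healthy library 2 or 3 or CD11b+ inflamed library 3 (adjusted p = 0.00778 to 0.0272 by camera; 0.0037 to 0.379 over the camera alternatives). Il1b, the cytokine IL-1 beta, was higher in CD11b+ cells (1121 ± 133 against 228 ± 41.5 CPM), and so were Il1rn (5.52 ± 0.62) and Tnf (1.86 ± 0.31). The chemokine Ccl17 (2.97 ± 0.55), the adaptor Samsn1 (1.31 ± 0.27), Tlr2, a sensor of bacterial lipoproteins (3.39 ± 0.28), Lpl, lipoprotein lipase (3.01 ± 0.32), the nuclear receptor Pparg (3.07 ± 0.51), the lactate transporter Slc16a3 (3.21 ± 0.60) and the transcription factor Spib (1.75 ± 0.35) were higher as well. Inflammatory cytokines, maturation, Toll-like receptor, lipid and glycolysis lists did not pass (limma's camera adjusted p = 0.0824, 0.0884, 0.130, 0.973 and 0.862). The cytokine list passed camera without CD103+ healthy library 1 or 3 (adjusted p = 0.0409 and 0.0225) and with leukocyte scaling (adjusted p = 0.0113; 0.0113 to 0.325 over the camera alternatives). The Toll-like receptor list passed camera without CD103+ healthy library 3 (adjusted p = 0.0393; 0.0393 to 0.571 over the camera alternatives).

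In CD103+ cells in nephritis, type I interferon genes rose for 16 of 24 and fell for 1, also adjusted over the list alone (median 1.32, or -0.25 with leukocyte scaling; limma's camera adjusted p = 0.00404, adjusted p = 0.383 with an estimated correlation). With leukocyte scaling 2 were higher and 4 lower. The restriction factor Trim30a rose by 2.44 ± 0.21 and the nucleic acid sensor Zbp1 by 2.26 ± 0.32. The protease Ctss rose from 300 ± 114 to 984 ± 35.3 CPM, a call lost with leukocyte scaling (0.20), and Lgmn, another lysosomal protease, fell from 558 ± 110 to 98.9 ± 18.9 CPM. The endothelial genes Kdr (-4.26 ± 0.79), Tie1 (-4.48 ± 0.91) and Ehd3 (-1.73 ± 0.32) fell, while the podocyte and endothelium list had 0 higher and 7 lower of 10, also adjusted over the list alone (limma's camera adjusted p = 0.0517, which did not pass). That list passed camera without CD103+ healthy library 1, CD103+ inflamed library 3 or CD11b+ inflamed library 1 or 3 (adjusted p = 0.0129 to 0.0478), with median-centred libraries (0.0436) and with a replicate block (0.0388), but not with an estimated correlation (adjusted p = 0.383; 0.0129 to 0.383 over the camera alternatives). The collagen gene Col1a1 rose by 3.29 ± 0.54 and the pericyte receptor Pdgfrb fell by 1.95 ± 0.66 on the log2 scale, a call lost without CD103+ healthy library 1 (-1.87) or 2 (-1.28) or CD103+ inflamed library 2 (-1.54) and with quantile normalization (-1.36). Fibroblast markers had 1 higher and 1 lower of 8, also adjusted over the list alone (limma's camera adjusted p = 0.865).

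Between the healthy subsets, MHC class II genes were higher in CD11b+ cells for 13 of 14 and lower for 1, also adjusted over the list alone (median 1.43; limma's camera adjusted p = 2.93e-06, adjusted p = 0.226 with an estimated correlation). With leukocyte scaling they came to 4 higher and 6 lower (median 0.06). Plasmacytoid markers had 6 higher and 1 lower of 9, also adjusted over the list alone (limma's camera adjusted p = 0.0104, adjusted p = 0.166 with an estimated correlation), or 1 and 3 with leukocyte scaling (median 0.13). Both erythroid and platelet genes measured were not tested as a list. The median and the mean differed in sign for matrix genes between the healthy subsets (-0.75 and 0.16, camera direction up), for lipid genes in the same comparison (-0.06 and 0.04, down) and in CD103+ cells in nephritis for regulatory T cell support (0.25 and -0.07, down), lipid genes (0.27 and -0.18, down) and B cell markers (-0.07 and 0.15, up). They also did so for maturation genes in CD11b+ cells in nephritis (-0.04 and 0.13, down) and, as given in the report, for macrophage markers in CD103+ cells. In the difference of responses, they did so for monocyte markers (-0.81 and 0.54, down). The camera direction was down against a median and mean above 0 for mitochondrially encoded genes between the inflamed subsets, and for chemokines and C-type lectins in the difference of responses.

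Each comparison between 2 groups allows 10 splits of its 6 libraries, too few splits for a share under 0.05: the real split alone gave as many calls (1 of 10) in each, and the highest other gave 1, 1, 0 and 1 for CD103+ cells, CD11b+ cells, the healthy subsets and the inflamed subsets.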
